A study of Homo sapiens with 4 samples.

How the data were processed

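Total RNA was extracted with TRIzol and sequenced on an Illumina platform, per the labels' protocols, from 4 cultures of human hepatocellular carcinoma lines. The lines were Huh7 and PLC/PRF/5. Each was stably transduced with a lentiviral short hairpin RNA against SCD1 (gene symbol SCD) or with a non-target vector, and selected with puromycin. There were 4 groups of 1 library each, and every group was assigned from the sample titles.

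The authors deposited a gene table per library with length-scaled transcript abundance (TPM), rounded to 2 decimals, by gene symbol. The submitters' processing notes name cutadapt, RSEM 1.2.21 and the hg19 build; the aligner, the gene annotation and the strand setting are not given in the sources used here. RSEM shares reads that match several genes among them by a likelihood model, so values of near-identical gene copies are uncertain. TPM divides by transcript length and sets each library to the same total, so a large change in a few abundant transcripts moves every other value, and the sequencing depth cannot be recovered. No counting interval or detection limit was therefore computed, and an exact 0 is reported as listed at 0.

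Log2 fold changes were computed per line as log2((knockdown TPM + 1)/(control TPM + 1)), a scale that understates the change of low genes. Within a line there is 1 library per arm, so the difference has no replicate check: genes with TPM of at least 1 in at least 1 library of the pair were counted when they differed at least 2-fold, which is a size rule and not a test. The replicated question is the knockdown difference common to the 2 lines. It was tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with cell line as a block, an empirical Bayes trend in the variance and 1 residual degree of freedom. The fit covered 13813 genes with TPM of at least 1 in at least 2 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment at 0.05. Nothing states that the libraries came from separate experiments, so p-values of single genes for the knockdown reflect how alike the 2 lines moved. Each also rests on a moderated variance, which combines the gene's 1 residual degree of freedom with 3.71 prior degrees of freedom. The prior comes from all genes of the fit, by their level, so a p-value is not set by the gene's own 2 differences alone. The cell line coefficient of the same fit gave the baseline comparison. Its p-values use the same residual and reflect how alike the line difference was in the 2 arms, not variation between replicate cultures. A design with 1 library per group allows no test of whether the knockdown acted differently in the 2 lines.

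The 19 gene lists, the designs and the rule for named genes were fixed before the data were examined. In each line, a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of those libraries. Across lines, lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with adjustment over the 19 lists. They were tested again with an estimated correlation. Camera compares the members of a list with all other genes, so its p-values do not measure how alike the 2 lines moved. With the estimated correlation it rests on the 1 residual degree of freedom, so a failure there is weak evidence against a list. Named genes were SCD and SCD5, and the 10 highest and 10 lowest fold changes in each line. They also included the 10 genes per direction with the largest smaller fold change of the 2 lines, the genes passing the fit, and up to 4 members per list, and any member of a list set out as a group. Of each list the 4 were those with the largest mean fold change over the lines; members named beyond them were chosen after their values were seen. For the baseline comparison they were the 10 largest differences per direction that passed, with ALB and AFP. A minimum of 5 TPM in at least 1 library applied, except to members of a list set out as a group, and short RNAs, XIST and Y-linked genes were left out. Some genes that this rule names are not reported here. Any gene named outside this rule is said to have been chosen after its values were seen.

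The alternatives were pseudocounts of 0.1 and 5, a TPM filter of 5 or none, rescaling of each library by its median ratio to the others, limma without the variance trend, and fits without the cell line or the arm term. Transcript length, GC content and shared sequence were taken from GENCODE 29 transcripts, to which 22677 symbols (89.5%) matched. That annotation is on another genome build than the authors' and was used for sequence properties only, so no coordinates are given. Shared sequence was measured as the percentage of 31-base words of a gene's longest transcript that also occur in another gene. Python 3.11.15 and matplotlib 3.10.9 were used for the sequence step and the plots.

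The across-line fit was tested on simulated data of 13813 genes with 200 changed genes, with the fitted line means and 2 choices of variance. With variances drawn from the prior distribution that limma estimated, the false calls are near nominal by construction, so this version checks recovery and not the error rate. It recovered 28% of 50 genes changed 2-fold, 88% of 50 changed 4-fold, 82% of 50 changed 8-fold and 86% of 50 changed 16-fold. Of all calls, 5.33% were unchanged genes. With each gene's moderated variance from the real fit, the version run first, recovery was 90%, 96%, 94% and 98%. In that version, however, 37 of 13613 unchanged genes were called, 16.4% of all calls. The adjusted p-values may therefore be too small. In both versions each changed gene was given the same true change in both lines. The percentages recovered therefore do not give the power of the fit for genes that moved unequally. In the real limma fit, SCD did not pass at a mean log2 fold change of -3.15 (adjusted p = 0.128). In the simulated Huh7 fold changes, with fewer random lists per comparison than in the analysis, 5.5% of 200 random lists of 25 genes with no shift lay outside the central 95% of random lists, and 100% did after a shift of 0.3. The simulated genes varied independently, whereas members of a fixed list can move together. The 5.5% is therefore not an error rate for the fixed lists.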

Results

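The data comprised 4 RNA-seq libraries, a vector control and an SCD knockdown library from each of Huh7 and PLC/PRF/5, lines derived from human hepatocellular carcinoma. The study asked which genes are expressed differently when SCD, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, is depleted. Among all gene symbols listed, 17582 had a TPM above 0 in the Huh7 control library and 17931 in the Huh7 knockdown library. The numbers for PLC/PRF/5 were 17405 and 17775. TPM carries no depth, so the depth of each library is unknown. Across the 13813 genes of the fit, log2 TPM correlated at r = 0.98 between the arms of Huh7, 0.99 between the arms of PLC/PRF/5 and 0.80 between the control libraries of the lines. These correlations are across genes, which are not independent replicates.

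SCD was lower in the knockdown library of both lines. Its level was 1755 TPM in the Huh7 control and 137 TPM in the Huh7 knockdown, 12.7-fold lower (log2 fold change -3.67). In PLC/PRF/5 it was 1111 TPM in the control and 178 TPM in the knockdown, 6.22-fold lower (log2 fold change -2.64). The mean over the lines was -3.15 with a standard error of 0.25, and it did not pass the across-line test in limma (adjusted p = 0.128). SCD5, the other human stearoyl-CoA desaturase gene, stood at 3.51 and 2.86 TPM in the Huh7 control and knockdown, and at 3.71 and 5.28 TPM in PLC/PRF/5.

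In Huh7, the highest fold change was that of the cancer-testis gene PAGE1 (log2 fold change 3.88), followed by EREG. EREG and AREG, which encode ligands of the EGF receptor, were at 2.63 and 6.89 TPM in the control and at 49.2 and 54.9 TPM in the knockdown. CXCL8, a neutrophil-attracting chemokine, was at 39.7 and 375 TPM, and EDN1, the precursor of the vasoconstrictor endothelin-1, at 5.21 and 40.9 TPM. The protease inhibitors PI3 and SLPI had log2 fold changes of 3.58 and 2.91, and TMEM45B and BAAT, a bile acid conjugating enzyme, of 3.12 and 2.81. Beside SCD, the lowest genes included BGN and CDC42EP5. The matrix protein genes BGN and SPARC had log2 fold changes of -3.44 and -2.55, the secreted protease HTRA3 of -3.12, CDC42EP5 of -3.57 and TSPAN18 of -2.54. Of 13485 genes considered, 418 were at least 2-fold higher and 207 at least 2-fold lower in the knockdown library. These are differences between single libraries with no replicate check.

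In PLC/PRF/5, the highest fold changes included the cancer-testis gene PAGE1 and the lowest the histidine-degrading enzyme gene HAL. PAGE1 was at 1.68 TPM in the control and 74.4 TPM in the knockdown, and SPANXB1 at 0.29 and 8.18 TPM. SCEL, a component of the cornified envelope, was at 5.2 and 36.3 TPM, and SYT13 and SHE had log2 fold changes of 2.65 and 2.51. At the low end, HAL was at 37.2 TPM in the control and 1.73 TPM in the knockdown. The hepatocyte fatty acid carrier FABP1 was at 23.1 and 2.64 TPM, the kininogen gene KNG1 at 34.1 and 5.33 TPM, and the acute-phase gene ORM1 at 240 and 49.1 TPM. CRH, which encodes corticotropin-releasing hormone, and the imprinted RNA H19 had log2 fold changes of -2.88 and -2.40. Of 13057 genes considered, 225 were at least 2-fold higher and 145 at least 2-fold lower, again between single libraries.

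Some extreme values came from genes that share most of their sequence with another gene and are uncertain. In Huh7 these were NPIPA3 (log2 fold change 2.74), SERF1A (-3.25), SLX1B (-3.15) and SULT1A4 (-3.14). In PLC/PRF/5 they were SMN2 (3.85), MAGEA9B (3.47), PAGE2B (3.41) and GAGE12D (-3.24), and ORM1 shares 56.1% of its sequence words with other genes. Values of -2.66 for XAGE1E, 4.22 for LOC101060389, -3.30 for LOC102723859 and 2.66 for LOC642423 belong to 4 symbols not matched to a transcript here. Among genes compared across the lines, SULT1A3 was higher in both lines (1.54 and 2.42) while its near-identical copy SULT1A4 was lower in both.

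Across both lines, the knockdown libraries shared higher EREG and CXCL8 and lower S100A9, SCD, CEACAM1 and B4GALT1. EREG had log2 fold changes of 3.79 in Huh7 and 2.07 in PLC/PRF/5, and CXCL8 of 3.21 and 1.54. PAGE1 differed most, at 3.88 and 4.81, from control levels of 0.79 and 1.68 TPM. HABP2, a plasma protease gene, had values of 2.60 and 1.68. The transcription factor genes ATF3 (1.63 and 1.34), KLF6 (1.28 and 1.58) and CREB5 (1.45 and 1.55), the desmosome-associated PPL (1.81 and 1.29) and WTIP (1.48 and 1.52) were also higher in both. On the lower side, S100A9, a calcium-binding alarmin, was at 132 TPM in the Huh7 control and 25.8 TPM in the knockdown, and at 565 and 122 TPM in PLC/PRF/5. The adhesion gene CEACAM1 had log2 fold changes of -1.58 and -1.59, and the galactosyltransferase gene B4GALT1 of -1.49 and -1.47. UBE2L6 (-1.35 and -1.70), SLC44A2 (-1.55 and -1.41), CNIH1 (-1.35 and -1.18), FAM174A (-1.23 and -1.31) and NEK7 (-1.20 and -1.29) completed the group.

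**Figure D1:**
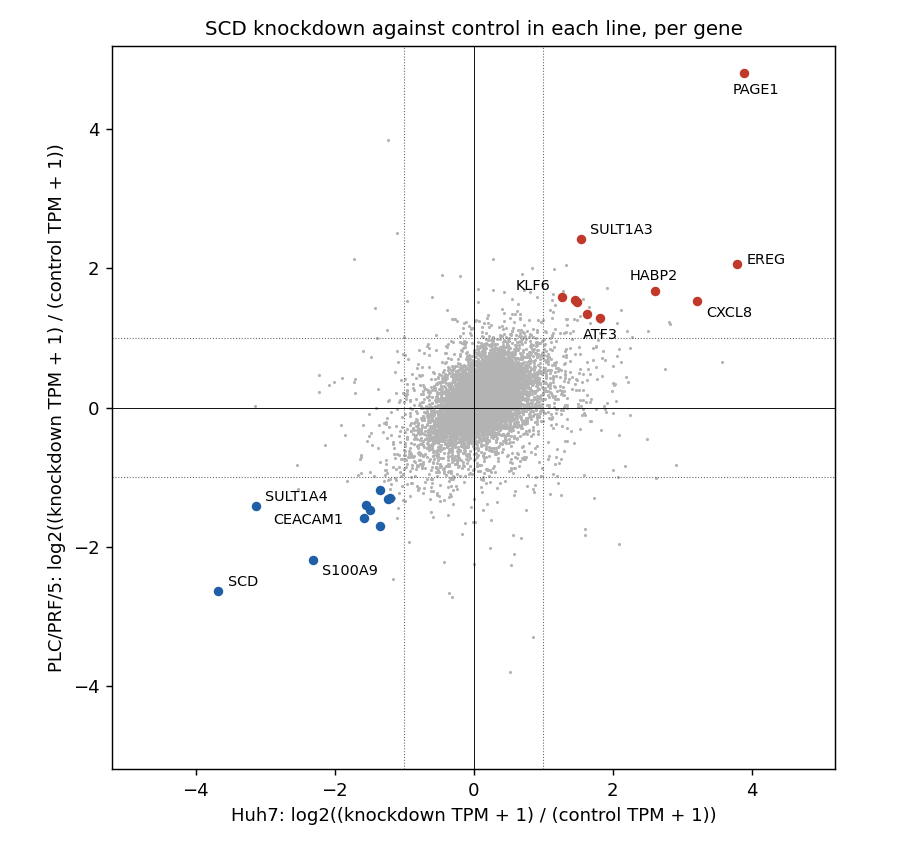
Log2 fold change of each gene in Huh7 (horizontal axis) and PLC/PRF/5 (vertical axis), knockdown over control on TPM + 1, for the 12064 genes considered in both lines, with dotted lines at 2-fold. Red and blue points are the 10 higher and 10 lower genes picked by the smaller of their fold changes; SCD lies at -3.67 and -2.64, and PAGE1 at 3.88 and 4.81.

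In the across-line limma fit, S100A9 fell, with a mean log2 fold change of -2.25, a standard error of 0.09 and an adjusted p = 0.046, lower in both lines. It was the 1 gene of 13813 to pass, and no gene passed on the higher side. The call was lost with a pseudocount of 5 (adjusted p = 0.0501), without a filter (adjusted p = 0.424), without the variance trend (adjusted p = 0.276) and without the cell line block (adjusted p = 1). The fit without the block keeps the difference between the lines, 2.15 on the log2 scale for S100A9, in its residual. At an unadjusted p under 0.05 there were 1759 genes higher and 724 lower, where chance gives 691 in all. Rescaling the libraries by median ratios changed this split from 70.8% higher to 45.7% higher.

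Differences in the 2 lines were correlated across genes. Among 12064 genes considered in both lines, Pearson's r between the fold changes was 0.41 and Spearman's rho 0.45, and 68.8% of genes had the same sign. Without SCD, r was 0.40. At the 2-fold size rule, 52 genes were higher in both lines, where independent lists of 293 and 159 genes give 3.86, and 26 were lower in both, where lists of 118 and 118 give 1.15. Another 8 genes were higher in Huh7 and lower in PLC/PRF/5 (2.87 by chance), and 7 the reverse (1.56 by chance). Among these opposite genes were short RNAs at 3.30 TPM or less in every library, and histone genes listed at 0 in at least 1 library. The chance numbers take the lists as independent and are not matched on expression. The median log2 fold change of all genes considered was 0.08 in Huh7 and 0.10 in PLC/PRF/5. Rescaling by median ratios shifted these by -0.08 and -0.10. With it, the higher share of 2-fold genes went from 66.9% to 58.8% in Huh7 and from 60.8% to 45.5% in PLC/PRF/5.

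Genes of the integrated stress response, the PERK-ATF4-CHOP arm of the reaction to ER stress, moved both ways, with several of its stress-induced regulators higher in both lines. ATF3 was at 6.91 and 23.4 TPM in the Huh7 control and knockdown and at 14.0 and 37.2 TPM in PLC/PRF/5. PPP1R15A, which restores translation, had log2 fold changes of 1.17 and 1.48, the transcription factor gene DDIT3 (CHOP) of 0.58 and 1.23, CHAC1 of 1.32 and 0.73, and SESN2 of 0.90 and 0.94. The serine synthesis genes PHGDH (-0.29 and -0.73) and PSAT1 (-0.31 and -0.21), the cystine transporter gene SLC7A11 (-1.12 and -0.27) and DDIT4 (-0.90 and -1.08) were lower in both. Of 23 members, 13 were higher in both lines, 5 lower in both and 5 opposite. Adjusted over the list alone, 9 members passed as higher and 2 as lower, and none did over all genes. The list's median was 0.38 in Huh7 (percentile 100) and 0.08 in PLC/PRF/5 (percentile 80.4); the latter became -0.03 with median-ratio scaling. The camera test did not pass (adjusted p = 0.294).

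ER chaperone and ER-associated degradation genes, targets of the ATF6 and IRE1-XBP1 arms, were higher in PLC/PRF/5. There, 26 of 27 members were higher, with a median of 0.52 (percentile 100). HERPUD1 was at 79.2 and 303 TPM, DNAJB9 at 50.7 and 134 TPM, and the chaperone gene HSPA5 (BiP) at 775 and 1383 TPM. In Huh7, 13 of 26 members were higher and 13 lower, with a median of -0.01 (percentile 32.2). HSPA5 was at 569 and 501 TPM there, while HERPUD1 (0.69), DNAJB9 (0.62), EDEM1 (0.73) and the IRE1 gene ERN1 (0.70) were higher. Adjusted over the list alone, 1 member passed as higher, and none over all genes. The camera test over both lines was upward (adjusted p = 0.0241), but adjusted p = 0.829 with an estimated correlation, here 0.85. XBP1 was at 1038 and 893 TPM in Huh7 and at 484 and 485 TPM in PLC/PRF/5, and its spliced form is not separated in gene-level values.

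**Figure D2:**
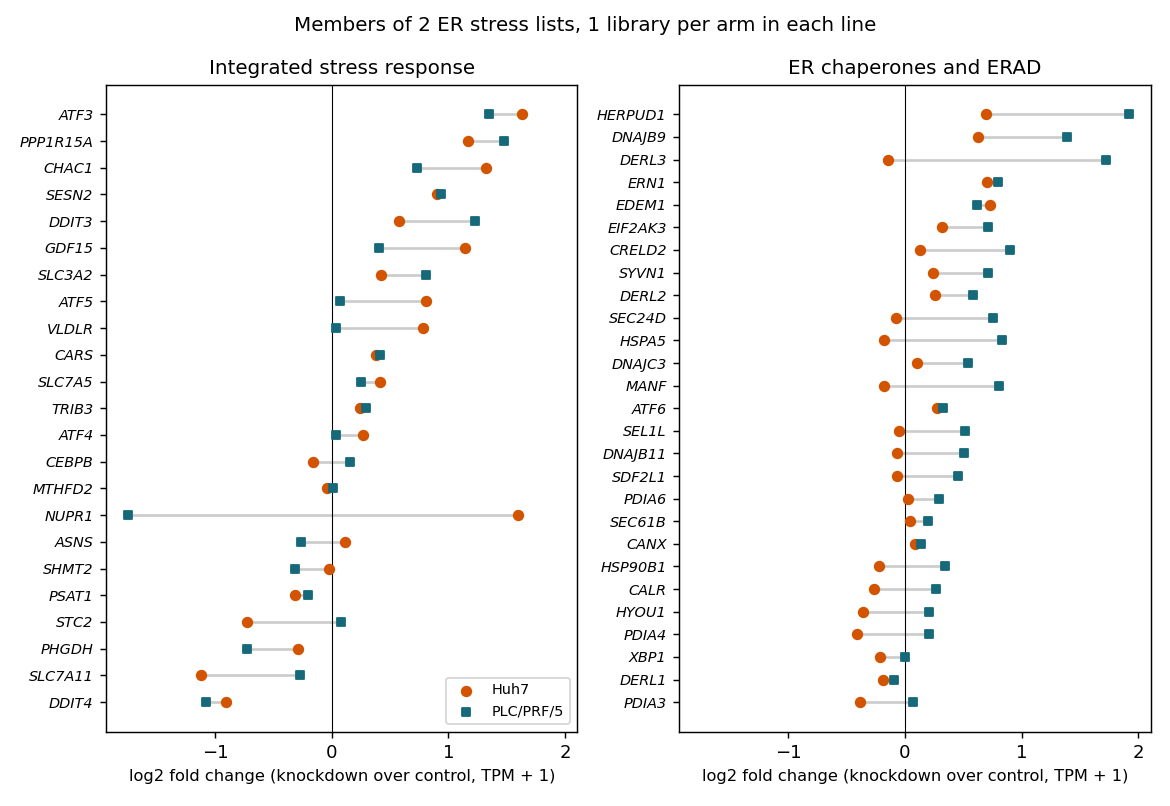
Log2 fold change (knockdown over control, TPM + 1) of each member of the integrated stress response list (left) and of the ER chaperone list (right), with circles for Huh7 and squares for PLC/PRF/5, 1 library per arm. ATF3 lies at 1.63 and 1.34, while HSPA5 lies at -0.18 in Huh7 and 0.83 in PLC/PRF/5 and NUPR1 at 1.60 and -1.75.

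Cholesterol synthesis and uptake genes, the targets of SREBP2, were slightly lower in Huh7 and higher in PLC/PRF/5. In Huh7, 22 of 25 were lower (median -0.16, percentile 0.15), and in PLC/PRF/5 20 of 24 were higher (median 0.33, percentile 100). Of the 24 considered in both lines, 21 had opposite signs. INSIG1, a sterol-sensing regulator gene, was at 164 and 126 TPM in Huh7 and at 66.0 and 175 TPM in PLC/PRF/5, and HMGCS1 had log2 fold changes of -0.08 and 0.69. Over both lines the list did not pass (camera adjusted p = 0.775), and no member passed over the list alone. Its median (0.02) and mean (0.10) over both lines were above 0, whereas camera, which compares a list with all other genes, placed it downward, and upward without the cell line block (adjusted p = 0.988).

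Fatty acid and glycerolipid synthesis genes other than SCD were lower in Huh7, with a median of -0.30 (percentile 0), and not displaced in PLC/PRF/5, with 0.02 (percentile 22.8), which became -0.09 with median-ratio scaling. The polyunsaturated fatty acid desaturase genes FADS2 and FADS1 and the elongase gene ELOVL6 were lower in both lines. FADS2 was at 1147 and 517 TPM in Huh7 and at 15.9 and 9.67 TPM in PLC/PRF/5, and FADS1 and ELOVL6 had log2 fold changes of -0.80 and -0.58 in Huh7 and -0.35 and -0.69 in PLC/PRF/5. FASN, fatty acid synthase, went from 694 to 545 TPM in Huh7 and from 323 to 401 TPM in PLC/PRF/5. With adjustment over the list alone, 2 of 23 members passed, both lower, and none over all genes. Camera was downward (adjusted p = 0.0241), but adjusted p = 0.783 with an estimated correlation. It also missed the threshold without the cell line block (adjusted p = 0.0644). Fatty acid oxidation and PPARA target genes did not pass (adjusted p = 0.344), with medians of 0.08 (percentile 62.1) and -0.03 (percentile 8.39). Their median over both lines was 0.05, their mean -0.05 and their camera direction downward. No member passed over the list alone. FABP1 had log2 fold changes of -0.31 and -2.72, and CPT1A, the mitochondrial carnitine transferase gene, of 1.28 and -0.04.

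Mature hepatocyte genes were lower in PLC/PRF/5, where 19 of 25 were lower (median -0.70, percentile 0), while 17 of 30 were higher in Huh7 (median 0.10, percentile 94.3). AHSG (fetuin-A) was at 35.7 and 6.73 TPM in PLC/PRF/5, and the fibrinogen gene FGB at 459 and 149 TPM. In Huh7 these genes were at 550 and 551 TPM, and at 901 and 1073 TPM. ALB went from 6498 to 10479 TPM in Huh7 and from 69.3 to 41.5 TPM in PLC/PRF/5. The transferrin gene TF was lower in both lines, with log2 fold changes of -0.61 and -1.14, and CYP2B6 was higher in both (2.12 and 1.41) from control levels under 1 TPM. Adjusted over the list alone, 2 members passed as higher and 3 as lower, and none over all genes. Camera was downward (adjusted p = 0.0069), but adjusted p = 0.829 with an estimated correlation and adjusted p = 0.0933 without the cell line block.

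Markers of progenitor and tumour-initiating cells split within the list. KRT19, a biliary keratin gene, was at 274 and 564 TPM in Huh7 and at 4.11 and 8.02 TPM in PLC/PRF/5, and KLF4 and CD44 had log2 fold changes of 1.85 and 1.01 in Huh7 and 0.71 and 0.85 in PLC/PRF/5. AFP, the fetal liver protein, was at 15421 and 10302 TPM in Huh7 and at 17.2 and 6.96 TPM in PLC/PRF/5. Adjusted over the list alone, 4 members passed as higher and 2 as lower, and none over all genes. The medians were -0.07 (percentile 7.17) and 0.28 (percentile 99.4), and the list did not pass in camera (adjusted p = 0.744), which placed it downward although its median and mean over both lines were 0.11.

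Cell cycle and DNA replication genes were lower in both lines. Of 30 members, 24 were lower in both, 2 higher in both and 4 opposite, and the medians were -0.20 in Huh7 and -0.21 in PLC/PRF/5 (percentile 0 in each). E2F1, a transcription factor of the G1/S transition, was at 89.0 and 43.3 TPM in Huh7 and at 70.6 and 35.9 TPM in PLC/PRF/5. TOP2A had log2 fold changes of -0.52 and -0.76 and MKI67, the Ki-67 gene, of -0.08 and 0.11. CCNE2, the cyclin E2 gene, was higher in both (0.80 and 0.67). Adjusted over the list alone, 5 members passed as lower and 1 as higher, and none over all genes. Camera was downward (adjusted p = 2.6e-11), but adjusted p = 0.783 with an estimated correlation, here -0.03 on 1 residual degree of freedom.

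Hypoxia and glycolysis genes had medians of -0.31 in Huh7 and -0.22 in PLC/PRF/5 (percentile 0 in each). Of 15 members considered in both lines, 6 were lower in both, 2 higher in both and 7 opposite. The glycolytic regulator gene PFKFB4 (-0.84 and -0.43), the lactate dehydrogenase gene LDHA (-0.48 and -0.38) and the collagen hydroxylase gene P4HA1 (-0.60 and -0.52) were lower in both. VEGFA was higher in both (0.56 and 0.42), and the stress-responsive NDRG1 had values of 0.68 and -1.88. Of 16 members, 2 passed as lower and 1 as higher adjusted over the list alone, and none over all genes. Camera was downward (adjusted p = 3.7e-04), but adjusted p = 0.783 with an estimated correlation. Targets of p53 and death receptor genes did not pass (adjusted p = 0.321), with medians of 0.16 (percentile 73.0) and 0.23 (percentile 90.4). Over the list alone 2 passed as higher and 1 as lower. GADD45A was at 26.7 and 52.3 TPM in Huh7 and at 52.5 and 101 TPM in PLC/PRF/5, BTG2 had log2 fold changes of 1.31 and 0.81, and the pro-apoptotic BAX of -0.54 and -0.93.

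Inflammatory and NF-kB target genes were the list with the highest median in Huh7, at 1.08 (percentile 100), with 0.48 (percentile 99.98) in PLC/PRF/5. Of 12 members considered in both lines, 9 were higher in both. Beside CXCL8, the members LTB (1.85 and 0.81), CXCL3 (2.18 and 0.44) and the feedback inhibitor genes TNFAIP3 (1.18 and 0.95) and NFKBIA (0.59 and 0.48) were higher, while ICAM1 was at -0.18 and -0.14. With adjustment over the list alone, 9 of 12 members passed as higher, and none over all genes. Camera was upward (adjusted p = 1.6e-04), but adjusted p = 0.783 with an estimated correlation. Interferon-stimulated genes did not pass (adjusted p = 0.294), with medians of 0.44 (percentile 99.1) and 0.23 (percentile 74.7) and no member passing over the list alone. IRF9 had log2 fold changes of 0.44 and 0.78 and IFI6 of -0.73 and -0.82.

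Antioxidant genes controlled by NRF2 moved both ways. HMOX1, heme oxygenase 1, was at 27.7 and 44.4 TPM in Huh7 and at 153 and 373 TPM in PLC/PRF/5, and OSGIN1 had log2 fold changes of 1.12 and 1.04, whereas the ferritin gene FTL had -0.23 and -0.65 and SLC7A11 -1.12 and -0.27. Over the list alone 6 of 17 passed as higher and 1 as lower. The medians were 0.27 (percentile 99.8) and 0.15 (percentile 94.5), and camera did not pass (adjusted p = 0.640). Wnt/beta-catenin targets had medians of -0.26 (percentile 0.21) in Huh7 and 0.31 (percentile 98.3) in PLC/PRF/5, and no member passed over the list alone. LGR5 was at 10.3 and 4.80 TPM in Huh7 and at 4.86 and 16.0 TPM in PLC/PRF/5. Camera did not pass (adjusted p = 0.545) and was downward although the median over both lines was 0.06 and the mean 0.01. ERK pathway feedback genes had medians of -0.19 (percentile 0.27) and 0.31 (percentile 99.3), and camera did not pass (adjusted p = 0.321). Over the list alone 1 member passed as higher. FOSL1 was higher in both lines (1.12 and 1.28), and EGR1 had values of -0.45 and 1.91.

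**Figure D3:**
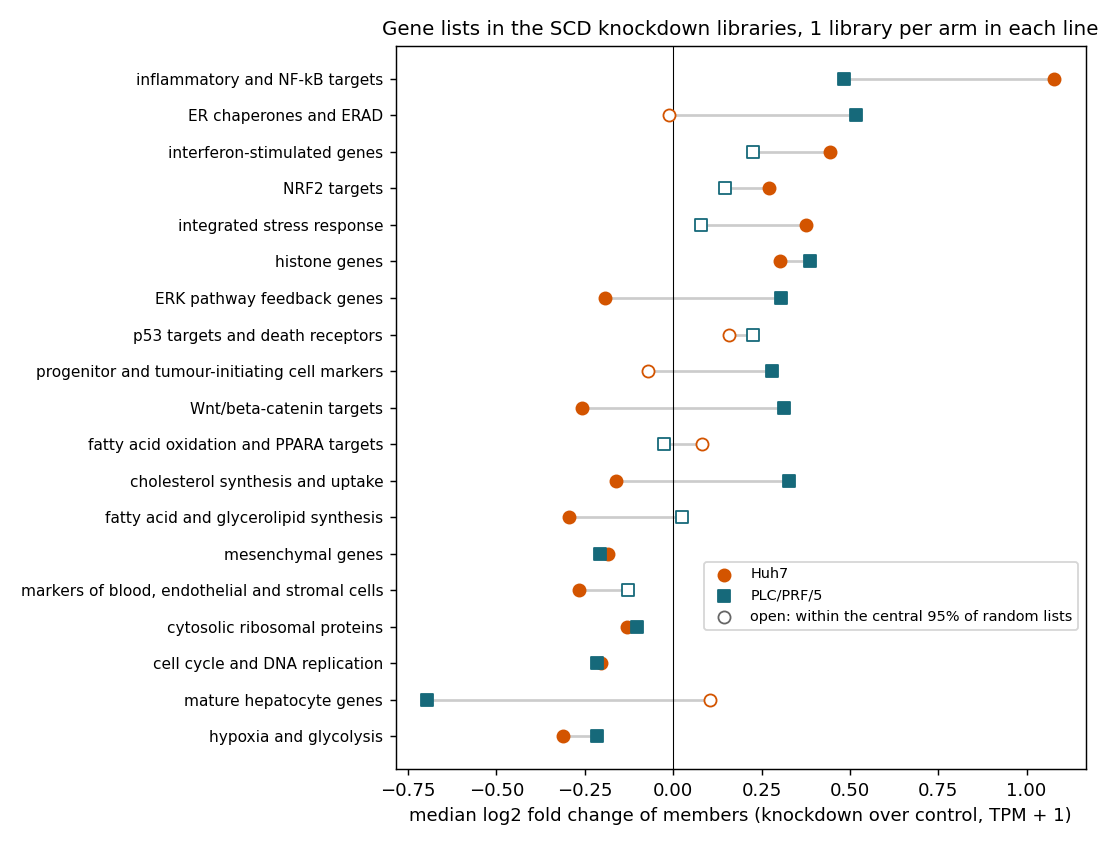
Median log2 fold change of the members of each of 19 gene lists (knockdown over control, TPM + 1), with circles for Huh7 and squares for PLC/PRF/5. Filled symbols lie outside the central 95% of 10000 random lists matched on expression, such as inflammatory and NF-kB targets at 1.08 and 0.48, and mature hepatocyte genes at -0.70 in PLC/PRF/5.

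Mesenchymal genes moved both ways, with 6 higher and 8 lower in Huh7 and 5 higher and 5 lower in PLC/PRF/5. Their medians were -0.18 (percentile 0.62) and -0.21 (percentile 0.87), the latter 0.063 without a filter, and they did not pass in camera (adjusted p = 0.208). LOX, a collagen crosslinking enzyme gene, had log2 fold changes of -0.92 and -1.27 and SPARC of -2.55 and -0.82, while TAGLN had 1.47 and 0.40. Over the list alone 3 passed as lower and 1 as higher. Of 16 markers of blood, endothelial and stromal cells, 6 were considered in Huh7 (median -0.27, percentile 2.44, and 0.080 without a filter) and 4 in PLC/PRF/5 (median -0.13, percentile 13.3). The list did not pass (adjusted p = 0.640), its camera direction turned upward without a filter (adjusted p = 0.989) and with a pseudocount of 0.1 (adjusted p = 0.966), no member passed over the list alone, and its mean over both lines was 0.09 against a median of -0.12. LUM, a matrix proteoglycan gene, was at 10.8 and 60.0 TPM in Huh7, and LYZ, lysozyme, at 1773 and 1008 TPM in Huh7 and at 1744 and 2600 TPM in PLC/PRF/5.

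Gene classes included as checks on RNA quality and library chemistry also differed between the arms, though no measurement of either was available here. Cytosolic ribosomal protein genes made up 14.8% of TPM in the Huh7 control and 13.4% in the knockdown, and 16.5% and 15.3% in PLC/PRF/5. Of 83 members, 66 were lower in both lines, with medians of -0.13 (percentile 0.105) and -0.10 (percentile 0.04). RPL3 and RPS29 were at 1809 and 1012 TPM in the Huh7 control and at 1315 and 764 TPM in the knockdown. Camera was downward (adjusted p = 3.5e-13), but adjusted p = 0.783 with an estimated correlation, and no member passed over the list alone. Histone genes made up 0.0948% and 0.120% of TPM in Huh7 and 0.0156% and 0.0228% in PLC/PRF/5. Their medians were 0.30 (percentile 99.8) and 0.39 (percentile 99.4). Camera did not pass (adjusted p = 0.0533), no member passed over the list alone, and HIST2H2BE was at 9.61 and 21.7 TPM in Huh7. The call was gained with median-ratio scaling (adjusted p = 0.0048), a pseudocount of 0.1 (adjusted p = 0.0368) and a TPM filter of 5 (adjusted p = 0.0044). The histone list still did not pass with a pseudocount of 5 (adjusted p = 0.0944) or without a filter (adjusted p = 0.321). Nor did it pass without the cell line block (adjusted p = 0.532) or with an estimated correlation (adjusted p = 0.783).

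The lines themselves differed far more than the arms. AFP stood at 15421 TPM in the Huh7 control and 17.2 TPM in the PLC/PRF/5 control (log2 difference over both arms -10.03, adjusted p = 1.4e-04), and ALB at 6498 and 69.3 TPM (log2 difference -7.24, adjusted p = 3.4e-04). Other genes higher in Huh7 in both arms were SPINK1, the mesenchymal filament gene VIM, IGF2, GNAS, CD7, MT1E, PTGR1, TTR and S100A6, with log2 differences from -9.43 for SPINK1 to -7.94 for S100A6. PLC/PRF/5 was higher in the cancer-testis genes XAGE1B, MAGEA2, MAGEA4, MAGEA3, MAGEA6 and CTAG2, and in BASP1, SPINT2, DSCAM-AS1 and CCK, from 8.80 for BASP1 to 7.13 for CCK. In limma, 4352 genes were higher and 3908 lower in PLC/PRF/5 at an adjusted p under 0.05, of which 2000 and 2053 differed at least 2-fold. Each line has 2 libraries, which differ in arm, so these p-values hold no variation between replicate cultures of a line.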

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

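The tests of trends below were specified before their results were seen, though after the patterns themselves; the test of genes with shared sequence was specified after individual copies had been seen.

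Several gene lists and genes lay on opposite sides in the 2 lines, and with 1 library per arm no difference between the lines was tested. Members of the fixed lists were taken up here only with at least 5 TPM in a library of each line, a minimum added after values were seen, which left out HIST1H4J and HIST1H4K. The median of the cholesterol synthesis list was higher in PLC/PRF/5 than in Huh7 by 0.49 on the log2 scale (-0.16 and 0.33). For Wnt/beta-catenin targets the difference was 0.57 (-0.26 and 0.31), and for ERK pathway feedback genes 0.50 (-0.19 and 0.31). Among genes at least 2-fold apart from control in opposite directions, AKR1C3, an aldo-keto reductase gene, had a difference of -3.63 (2.62 in Huh7 and -1.01 in PLC/PRF/5). NUPR1, a stress-induced gene, had -3.34 (1.60 and -1.75), and the Wnt antagonist gene DKK1 had 2.35 (-1.24 and 1.11). The difference was 3.60 for SHE (-1.10 and 2.51) and 5.09 for SMN2 (-1.24 and 3.85), the latter a gene with a near-identical copy.

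The cholesterol synthesis, ER chaperone and mature hepatocyte lists were weighed against a trend of fold change with abundance, transcript length or GC content. After such trends were removed in each line, the difference of medians was 0.49 for cholesterol synthesis (bootstrap SE 0.08), 0.53 for ER chaperones (SE 0.09) and -0.67 for mature hepatocyte genes (SE 0.24). Before the removal these were 0.49, 0.53 and -0.80, so the trends do not account for the differences of these 3 lists. The Wnt and ERK lists were not weighed in this way. The bootstrap resampled list members, so its SEs hold no variation between cultures or libraries. A difference between the lines in their reaction to SCD loss stays open as an untested biological explanation. Handling of a single culture cannot be told apart from it, because there is 1 library per arm in each line and the labels give no batch.

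The correlation of the knockdown differences in the 2 lines was weighed in the same way. Pearson's r was 0.41 before and 0.40 after the trends were removed (bootstrap over genes, SE 0.02, 11304 genes), which argues against those trends as its source. Of 83 ribosomal protein genes, 66 were lower in both lines, though the call of that list was lost with an estimated correlation (adjusted p = 0.783). The histone list did not pass in camera (adjusted p = 0.0533), but did with median-ratio scaling (adjusted p = 0.0048), a pseudocount of 0.1 (adjusted p = 0.0368) and a TPM filter of 5 (adjusted p = 0.0044). With a pseudocount of 5 (adjusted p = 0.0944) and without a filter (adjusted p = 0.321) the histone list did not pass. The same held without the cell line block (adjusted p = 0.532) and with an estimated correlation (adjusted p = 0.783). A batch shared by the knockdown libraries, an effect of the hairpin on other transcripts and an effect of SCD loss cannot be told apart here, since the labels name 1 hairpin and arm would coincide with any such batch.

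Extreme fold changes of genes that share sequence with others may come from reads that were divided differently among them. Of 10 such genes sharing over 50% of their words with a partner, 8 share at least 96.5%, while PAGE2B shares 62.6% and ORM1 56.1%. For 80% of the 10, all but PAGE2B and ORM1, the sum with the partners differed less than 2-fold on TPM + 1. Without the added 1 it was 70% of genes, and 6 of 9 distinct sums, since SULT1A3 and SULT1A4 share a sum, so the explanation stays open for the set. In PLC/PRF/5, SMN2 with SMN1 was at 43.1 and 52.3 TPM, MAGEA9B with MAGEA9 at 9.21 and 18.6 TPM, PAGE2B with PAGE2 at 3.40 and 36.4 TPM, and ORM1 with ORM2 at 281 and 58.0 TPM.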

How the results depend on the processing

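The direction of the SCD difference was kept in both lines under both other pseudocounts and median-ratio scaling, from -3.75 to -3.63 in Huh7 and from -2.75 to -2.61 in PLC/PRF/5. Counts of 2-fold genes followed the pseudocount, which by construction sets how far low genes can move. With 0.1 there were 695 higher and 370 lower genes in Huh7, 480 and 248 in PLC/PRF/5, and 125 in the same direction in both lines. With 5 the numbers were 155, 92, 68, 55 and 26. The correlation between lines was 0.35 and 0.44 with these pseudocounts, 0.47 with a TPM filter of 5 and 0.33 without a filter; the cause was not tested.

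In the limma fit, 1 gene, PAGE1, passed as higher with a pseudocount of 0.1 (adjusted p = 0.0269). The number of lower genes was 0 with a pseudocount of 5, without a filter and without the variance trend, and the cause was not tested. It was also 0 without the cell line block. There the difference between the lines enters the residual, so that fit says little about how robust the call is. Over all alternatives the adjusted p of S100A9 ranged from 0.0269 to 1. The counts of genes differing between the lines stayed within 1.5 times under every alternative run. Of 7 lists passing in camera, 0 passed with the estimated correlation, a version that rests on 1 residual degree of freedom. The calls of the cell cycle, hypoxia and ribosomal protein lists were lost at estimated correlations of -0.03, -0.05 and 0.07. The estimates were 0.11 for fatty acid synthesis, 0.39 for NF-kB targets, 0.43 for mature hepatocyte genes and 0.85 for ER chaperones, against the preset 0.01. The losses therefore do not by themselves show an effect of correlation among members. Nor do they exclude it for the lists with high estimates, whose calls rest on the preset value. Without a filter, the median became 0.063 for mesenchymal genes in PLC/PRF/5 and 0.080 for markers of blood, endothelial and stromal cells in Huh7, a turn of sign in each; the cause was not tested.

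No 2-fold difference of a named gene changed sign under the pseudocounts or the scaling. Leaving out a line leaves the values of the other line with no test. With the cell line as block the fit is a paired comparison, and the unpaired alternative is the fit without that block. TPM keeps no depth, so the precision of low values is unknown.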

Other observations

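The genes in this part were chosen after their values were seen, and none passed the across-line test. Beside EREG and AREG, the EGF receptor gene EGFR was higher in both knockdown libraries, at 99.0 and 174 TPM in Huh7 and at 70.1 and 112 TPM in PLC/PRF/5, as was the ligand gene HBEGF (log2 fold changes 0.67 and 1.29). The transcription factor gene JUN had log2 fold changes of 0.67 and 0.96. CYR61, a matrix-associated signalling protein gene, was at 51.3 and 184 TPM in Huh7 and 36.5 and 87.3 TPM in PLC/PRF/5, and ANKRD1 at 55.7 and 235 TPM and 1.88 and 3.82 TPM. CTGF, of the same family as CYR61, was lower in both knockdown libraries, at 232 and 166 TPM in Huh7 and 75.1 and 42.6 TPM in PLC/PRF/5.

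The metallothionein gene MT2A was at 448 and 846 TPM in the Huh7 control and knockdown, MT1G at 105 and 343 TPM and MT1F at 129 and 286 TPM; the family was not tested. In PLC/PRF/5, MT2A was at 22.6 and 20.8 TPM and MT1G was listed at 0 in both libraries. The difference between the lines was not tested. Among the genes at least 2-fold apart in opposite directions, IGFBP3, which binds insulin-like growth factors, was at 8.73 and 40.5 TPM in Huh7 and at 81.4 and 20.2 TPM in PLC/PRF/5. CYP24A1, the vitamin D-degrading enzyme gene, was at 0.26 and 1.69 TPM in Huh7 and at 72.3 and 30.0 TPM in PLC/PRF/5.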
